A study of Mus musculus with 4 samples.

How the data were processed

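RNA was measured in 4 libraries of mouse neocortex (C57BL/6) dissected at E13.5. Per the labels, 2 libraries came from Upf2fl/fl Emx1-Cre+ embryos (replicates 4 and 5) and 2 from Upf2fl/+ Emx1-Cre- embryos (replicates 8 and 9), and the series describes the controls as littermates. Per the labels' protocols, total RNA was extracted with TRIzol, treated with DNase, required to have a RIN of at least 9.0, and made into libraries with the TruSeq Stranded Total RNA kit. Alignment used STAR and the mm10 build, per the submitters' processing notes. The gene counter, its strand setting, the annotation release and the tool that computed TPM are not given in the sources used here.

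The authors deposited 1 table of TPM values (transcripts per 1000000) with 40630 genes, and each of its 4 columns sums to 1000000. Gene IDs were compared with GENCODE M21 names (mouse build GRCm38, the same assembly as mm10), in which 40227 IDs (99.0%) matched with their version and 40513 without it. A spreadsheet had turned 27 gene symbols into dates, and these were restored from their IDs. Symbols that occurred again were kept for the most abundant row, and the other 49 rows carried their ID in the name.

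Depth was worked out from the deposited TPM. Each value multiplied by the gene's merged exon length in GENCODE M21 was a whole multiple of 1 step per library, within a tolerance of 0.05 reads, for 100.0% of values above 0. The recovered totals were 33537843 and 36453920 reads for the cKO-labelled replicates 4 and 5, and 41680052 and 38274835 for the control replicates 8 and 9. The 349 genes without an M21 length of the same ID version, Zfas1 among them, have no recovered reads and held 0.556% to 0.772% of each library's TPM. The annotation release is therefore inferred from the values. The chi-square per gene between recovered reads was 35.8 for the cKO-labelled pair and 230.4 for the control pair, so no pair agreed within sampling noise and each library was counted as 1 sample.

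Fold changes are differences of mean log2(TPM + 1), cKO-labelled minus control. The pseudocount of 1 makes them understate the change of low genes. Genes with a mean TPM of at least 1 over the 4 libraries (15107 genes) were tested with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and an intensity trend, two-sided, and Benjamini-Hochberg adjusted p-values were called under 0.05. Every adjusted p printed for a gene is from limma. The estimated prior degrees of freedom were infinite, so the spread of each gene was the value of the pooled trend and the standard errors do not reflect a gene's own replicates. They were finite with no filter on low TPM (4.95), without control replicate 8 (7.22) or 9 (7.64) and after GC removal (5.87), so a gene's own spread counts in those fits. An exact permutation test of 2 libraries against 2 cannot go below p = 0.333 and was not used for single genes.

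A total of 30 gene lists were fixed before the data were examined, as were the test, the alternatives and the rule for named genes. Lists with at least 5 tested members (28 of 30) were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 28 lists. The alternatives to camera at the preset correlation were camera with an estimated correlation and fry. Member counts were adjusted over all tested genes and, separately, over the list alone.

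The lists covered NMD factors, the exon junction complex, known NMD target genes, splicing regulators with poison exons, p53 targets, the integrated stress and unfolded protein responses, apoptosis, DNA repair, S phase, G2 and M phase, primary microcephaly genes, ribosomal proteins, mitochondrial mRNAs, signalling readouts, interferon-stimulated genes, immediate early and heat shock genes, and hypoxia and glycolysis genes. Marker lists covered apical radial glia, intermediate progenitors, projection neurons, Cajal-Retzius cells, ganglionic eminence and interneurons, cortical hem and choroid plexus, thalamus, microglia and macrophages, endothelium and pericytes, meninges, red blood cells, and oligodendrocyte precursors with astrocytes. The last list held sex-specific genes.

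Genes were named by a rule. It took Upf2, Upf1, Upf3a and Upf3b, and the 12 higher and 12 lower called genes of largest absolute fold change whose cKO-labelled libraries lay outside the control range and whose mean TPM was at least 5, leaving out unnamed gene models. From each list it took up to 4 members of smallest p and, for lists not called, up to 2 of the most abundant, and it took the sex-specific genes. The rule gave 158 genes, of which 2 are not reported here. A further 13 genes outside it were chosen after their values were seen: Snhg1, Snhg5, Snhg8, Snhg15, Pdrg1, Ddit3, Slc7a5, Nupr1, Cdkn1a, Mdm2, Hes1, Lhx2 and Emx1. Most complete a list's count of called members.

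The alternatives were pseudocounts of 0.1 and 0.5, no filter on low TPM, a mean TPM of at least 5, median-of-ratios scaling, quantile normalization, removal of mitochondrially encoded genes, limma without the trend, robust empirical Bayes, an added fold change threshold of 1 on the log2 scale, limma with voom weights on the recovered reads, and each library left out in turn. Without 1 library, the lone library of its group was assumed to vary like the pair of the other group. The removal of a GC trend from each library (a lowess curve with span 0.3 of its deviation from the gene mean against the GC content of the gene's longest transcript), with and without control replicate 9, was chosen after seeing the data.

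The steps were tested on simulated data for this comparison, with 200 of 15107 genes changed in each of 10 runs. At the spread of these libraries limma recovered 24.2% of simulated changes of 1 on the log2 scale, 97.8% of changes of 2 and 99.8% of changes of 3. Only genes at about 5 TPM or more were changed, so these shares do not cover lower genes. Of its calls 4.9% were false. Noise was drawn independently per gene from the spread that limma had fitted, without a GC trend between libraries. The false share was therefore largely set by the simulation and may be higher in the data. For lists of 30 genes shifted by 0.5, camera at the preset correlation called 10 of 10, fry 3 of 10 and camera with an estimated correlation 0 of 10, and none called any of 200 unshifted lists. Data handling used Python 3.11.15 with NumPy 2.4.6 and pandas 2.3.3, and plots used Matplotlib 3.10.9.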

Results

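The data were 4 RNA-seq libraries of embryonic mouse neocortex at E13.5, a stage when cortical progenitors produce deep-layer neurons. Emx1-Cre is a recombinase expressed from early stages in the dorsal telencephalon, and Upf2 encodes an adaptor protein of nonsense-mediated mRNA decay (NMD), the pathway that degrades transcripts with premature or otherwise unusual stop codons. One group held 2 libraries labelled as Upf2 conditional knockout (cKO; Upf2fl/fl with Emx1-Cre) and the other 2 libraries of controls (Upf2fl/+ without Cre), so the presence of Cre and the number of floxed alleles differ together. Recovered depth was 33537843 and 36453920 reads in cKO-labelled replicates 4 and 5, and 41680052 and 38274835 in control replicates 8 and 9. The labels do not say that each library is a separate embryo, so p-values cannot be read as measuring variation between embryos. In the main fit they rest on a spread pooled over genes, not on that of a gene's own replicates.

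The comparison asked which transcripts differ in the neocortex of Emx1-Cre Upf2 cKO embryos. Upf2 itself (ENSMUSG00000043241.14, chromosome 2, 5951469 to 6056703 in GRCm38) was not lower in the libraries labelled cKO. Its level was 27.8 and 42.2 TPM in cKO-labelled replicates 4 and 5 and 23.7 and 41.3 TPM in control replicates 8 and 9 (log2 fold change 0.13 ± 0.36 (SE), limma adjusted p = 0.853). The value of the whole gene does not check the deletion, because a floxed segment is only part of a gene, the labels do not say which exons it holds, and cells without Cre keep it. The direction turned when a library was left out, to -0.16 without cKO-labelled replicate 5 and -0.26 without control replicate 8, while it was 0.42 without cKO-labelled replicate 4 and 0.52 without control replicate 9. After removal of a GC trend, chosen after seeing the data, Upf2 stood at 0.58 (adjusted p = 0.0903, the smallest of 16 alternatives), and at 0.64 with control replicate 9 also left out. The groups are therefore called cKO-labelled and control throughout.

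Transcripts of tissues at the edge of the cortex differed most. The median marker of the cortical hem and choroid plexus had 0.3 TPM in both cKO-labelled libraries against 14.5 and 16.9 TPM in controls, and meningeal markers were lower too. Markers of the ganglionic eminences, the ventral source of interneurons, were higher. Of 34 known NMD targets 9 rose, led by the lncRNA Zfas1 at 603 and 1677 TPM against 75.1 and 95.1 TPM in controls and with the stress response factor Atf4 at 3.77 times its control mean, and the list was higher, a call that ended with an estimated correlation (camera adjusted p = 0.644), as did those of all other lists. The list of p53 targets did not pass its test.

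Of 15107 genes tested, 1229 changed, 438 higher and 791 lower (limma, adjusted p under 0.05), and 3439 had an unadjusted p under 0.05. Among the lower genes 48 had a log2 fold change under -3, against 2 higher genes over 3. The median of all tested genes was -0.16, and it was -0.01 after median-of-ratios scaling or quantile normalization. These scalings changed the split from 35.6% of calls higher to 52.6% and 57.2%. The groups did not overlap for 57.6% of tested genes. Chance gives 33.3% for a single gene, but genes share trends between libraries, so the excess is no test of a group effect.

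The counts depended on single libraries. Without cKO-labelled replicate 4 there were 176 calls and without replicate 5 there were 269, fits in which the spread comes from the control pair alone. Without control replicate 8 there were 7379 calls, with the spread taken from the cKO-labelled pair, and without control replicate 9 there were 885, with 498 lower. Of the 81 named genes that passed the threshold, 18 passed without any 1 library: Ttr, Clic6, Rspo1, Wnt8b, Kcne2, Dynlrb2, Sulf1, Cldn11, Lum, Col3a1, Col1a1, Col1a2, Pdgfra, Pf4, Mrc1 and Hey2, all lower, and Sst and Zfas1, both higher. None of the 81 changed direction in these fits. That is little support, because leaving out 1 library cannot turn the sign of a gene whose groups do not overlap. Of the 1229 called genes 1214 were such genes. Of the 87 other named genes in those fits, 55 passed without control replicate 8 and 5 without control replicate 9.

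Control replicate 9 stood apart from the rest. Across genes, its log2 difference from control replicate 8 had a Spearman correlation of -0.76 with the GC content of the gene, and genes are not independent replicates. With the genes in 5 groups by GC content, it lay 0.64 above the gene mean on the log2 scale in the lowest group (median 41.3%), and at -0.47 in the highest (median 57.9%). The fold change between the cKO-labelled and control libraries had a correlation of 0.54 with GC content. After removal of the GC trend, an alternative chosen after seeing the data, 1323 genes were called, 615 higher and 708 lower, and 792 of the 1229 calls remained in the same direction.

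**Figure D1:**
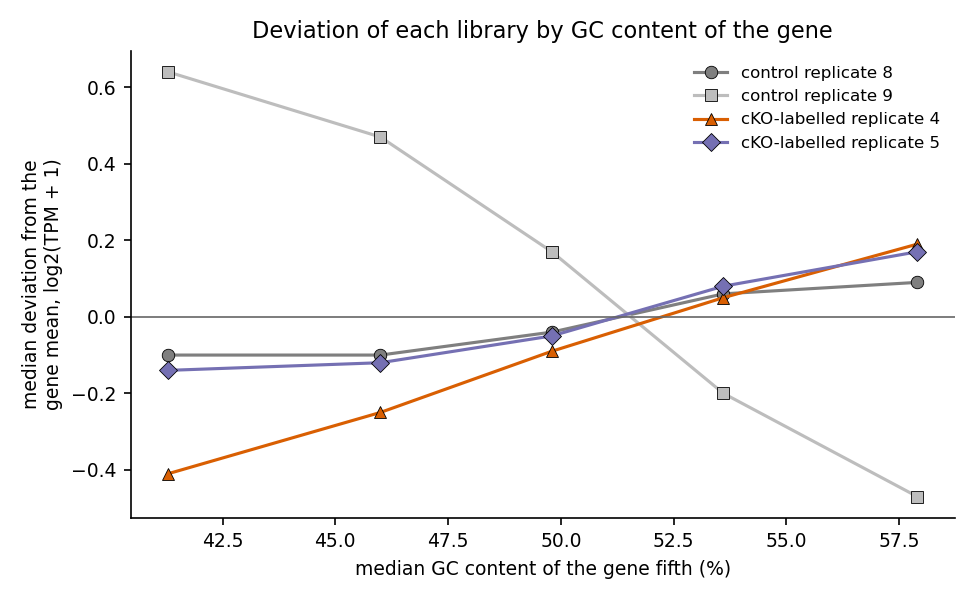
Median deviation of each library from the gene mean, in log2(TPM + 1), against the median GC content (%) of 5 groups of the tested genes by GC content; each line is 1 library. Control replicate 9 runs from 0.64 at a GC content of 41.3% to -0.47 at 57.9%, while cKO-labelled replicate 4 runs the other way, from -0.41 to 0.19.

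All 23 tested members of the cortical hem and choroid plexus list fell, and all 23 did so adjusted over the list alone (median log2 fold change -3.17, camera adjusted p = 4.77e-107; adjusted p = 0.202 with an estimated correlation). Ttr, the thyroid hormone carrier secreted by choroid plexus (ENSMUSG00000061808.4, chromosome 18, 20665280 to 20674321), had 1.49 and 1.45 TPM in the cKO-labelled libraries and 1862 and 2018 TPM in controls (-9.62 ± 0.35 (SE), adjusted p = 5.3e-163), which rested on 18 and 19 reads against 28194 and 26524. The choroid plexus channel gene Clic6 had 0.28 and 0.02 TPM against 32.8 and 47.0, and the hem Wnt signalling genes Rspo1 and Wnt8b stood at -4.91 and -4.70. Outside the list, the choroid plexus potassium channel gene Kcne2 fell to 0 and 0.15 TPM (0 and 3 reads) against 19.6 and 48.2 TPM, and the dynein light chain gene Dynlrb2 to 0.53 and 0.16 TPM (3 reads and 1 read) against 45.8 and 31.2 TPM. Sulf1, a heparan sulfate editing enzyme gene, stood at -4.56. Without cKO-labelled replicate 4 or 5, 17 and 19 of the list's calls remained.

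Of 27 tested meningeal and mesenchymal markers 21 fell and none rose, and 22 fell adjusted over the list alone (median -2.16, camera adjusted p = 3.53e-55; adjusted p = 0.202 with an estimated correlation). Lum, a small proteoglycan of connective tissue, had 0.24 and 0.04 TPM against 55.5 and 60.3 TPM in controls. The collagen genes Col3a1, Col1a1 and Col1a2 stood at -5.03, -4.91 and -4.53. Cldn11, a tight junction gene of the arachnoid barrier outside the list, fell to 0.89 and 0.39 TPM against 63.5 and 40.6 TPM. Without cKO-labelled replicate 4 or 5 or control replicate 8, 16, 18 and 20 of the list's calls remained.

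Among 21 microglia and macrophage markers 3 fell and none rose, with 8 lower adjusted over the list alone (median -0.56, camera adjusted p = 0.000965; adjusted p = 0.737 with an estimated correlation). The 3 were Pf4, Mrc1 and Lyz2, genes known from macrophages of brain borders, at -2.72, -2.39 and -1.95. The microglial gene Tmem119 did not pass (-1.01, limma adjusted p = 0.0768), and stood at -0.32 without control replicate 8 and -1.70 without control replicate 9. Of the 21 members, 20 had a negative fold change. Lyz2 missed the threshold without cKO-labelled replicate 4 (adjusted p = 0.364) or 5 (adjusted p = 0.0865), in a range of 4.76e-06 to 0.364 over 16 alternatives. The list's call ended without control replicate 8 (adjusted p = 0.783), in a range of 1.3e-09 to 0.783 over 18 alternatives. Its median was -0.30 without cKO-labelled replicate 4, -0.32 without control replicate 8 and -0.91 without control replicate 9.

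Of 30 ganglionic eminence and interneuron markers 20 rose and none fell, and 21 rose and 1 fell adjusted over the list alone (median 1.29, camera adjusted p = 8.01e-26; adjusted p = 0.602 with an estimated correlation). Nkx2-1, the medial ganglionic eminence regulator (ENSMUSG00000001496.15, chromosome 12, 56531958 to 56536908), had 44.2 and 3.73 TPM against 0.22 and 1.11 TPM in controls (3.19 ± 0.37 (SE), adjusted p = 4.12e-15). That SE is the value of the pooled trend and does not reflect the spread of the gene's own replicates. Over 16 alternatives the adjusted p of Nkx2-1 ranged from 1.81e-20 to 0.416. The largest came with robust empirical Bayes on all 4 libraries, where the call ended. It also ended without control replicate 8 or 9, where the fold change was 2.79 and 3.58. The fold change was 1.56 without cKO-labelled replicate 4 and 4.82 without replicate 5. The interneuron peptide genes Sst and Npy rose by 2.84 and 2.37 on the log2 scale, the vesicular GABA transporter gene Slc32a1 by 2.52, and the regulators Dlx2, Dlx5, Gsx2 and Lhx6 by 2.82, 2.31, 2.32 and 2.39. Lhx6 was at 1.58 without cKO-labelled replicate 4, and Dlx5 and Gsx2 were at 1.53 and 1.43 without control replicate 8. Ntn1, an axon guidance cue gene outside the list, rose by 2.47, a call lost without cKO-labelled replicate 4.

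The ganglionic eminence markers also differed within the groups. All 20 risen members were higher in cKO-labelled replicate 4 than in replicate 5, and 24 of 30 members were higher in control replicate 9 than in 8. Without cKO-labelled replicates 4 and 5 and control replicates 8 and 9 in turn, 2, 13, 7 and 16 of the 20 calls remained. The median of the list was 0.76 without control replicate 8 and 2 without control replicate 9. After removal of the GC trend the median was 1.50, with 9 members called and 6 of the 20 calls kept.

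**Figure D2:**
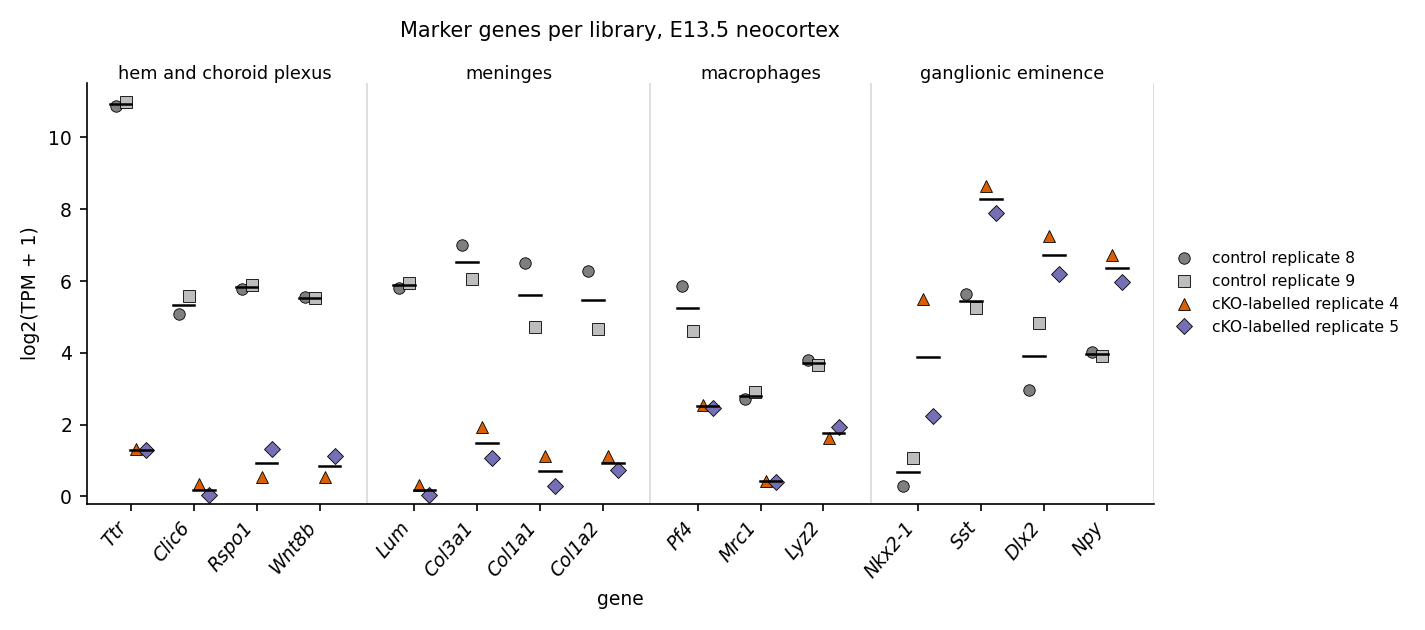
Level of marker genes in each library, in log2(TPM + 1), with 1 point per library and a bar at the mean of each group of 2. Ttr lies at 1862 and 2018 TPM in controls and at 1.49 and 1.45 TPM in the cKO-labelled libraries, and Sst at 48.7 and 36.8 TPM in controls and at 402 and 239 TPM in the cKO-labelled libraries.

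Of 34 known NMD target genes 9 rose and 1 fell, with the same counts adjusted over the list alone (median 0.42, or 0.58 above the median of all genes; camera adjusted p = 4.64e-08; adjusted p = 0.644 with an estimated correlation). Zfas1, a snoRNA host lncRNA (ENSMUSG00000074578.14, chromosome 2, 167062934 to 167065862), had 603 and 1677 TPM against 75.1 and 95.1 TPM in controls (3.56 ± 0.35 (SE), adjusted p = 4.33e-21). The snoRNA host Snhg12 had 92.0 and 316 TPM against 21.1 and 26.0 (2.81, adjusted p = 1.56e-13). The hosts Snhg15, Snhg1, Snhg8 and Snhg5 rose by 1.53, 1.45, 1.42 and 1.31. The cKO-labelled replicate 5 carried much of these rises: without it they were 0.44, 0.76, 0.93 and 0.58, and without cKO-labelled replicate 4 Snhg15 and Snhg5 were at 2.62 and 2.05. Pdrg1 and the stress regulator gene Ddit3 rose by 1.08 and 1.45, and Robo3, an axon guidance receptor gene with an NMD-sensitive isoform, stood at -1.70 as the member that fell. Without cKO-labelled replicates 4 and 5 and control replicates 8 and 9 in turn, 3, 1, 7 and 7 of the 10 calls remained, and Zfas1 remained in each. The list's median was 0.23 without cKO-labelled replicate 5.

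Of 33 integrated stress response and unfolded protein response genes 5 rose and 2 fell, or 7 and 3 adjusted over the list alone (median 0.42, or 0.57 above all genes; camera adjusted p = 0.000965; adjusted p = 0.737 with an estimated correlation). Atf4, the central transcription factor of the integrated stress response and a known NMD target (ENSMUSG00000042406.8, chromosome 15, 80255184 to 80257541), had 775 and 1070 TPM against 226 and 264 TPM in controls (1.90 ± 0.36 (SE), adjusted p = 1.19e-05). That call ended without cKO-labelled replicate 4 (adjusted p = 0.168) or 5 (adjusted p = 0.39), in a range of 2.43e-06 to 0.39 over 16 alternatives. Chac1, Atf5, Ddit3 and the amino acid transporter gene Slc7a5 rose, by 1.69, 1.48, 1.45 and 1.01. Atf4 and Ddit3 are also risen members of the known NMD target list, so the calls of the 2 lists are not independent. The cystathionine lyase gene Cth and the stress gene Nupr1 fell, at -1.59 and -1.01. None of the 7 calls remained without cKO-labelled replicate 4 or 5, fits with 176 and 269 calls in all, and 5 remained without control replicate 9. Without that control the list's median was 0.24, or 0.29 above all genes, and Slc7a5 was at 0.61.

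Of 13 genes on the list of NMD factors 1 rose and none fell, or 1 and 1 adjusted over the list alone (median 0.13, or 0.28 above all genes, with camera adjusted p = 0.0707). That median was -0.01 without control replicate 8 and 0.44 without control replicate 9, or 0.23 and 0.49 above all genes. The riser was Smg9, which encodes a regulator of the SMG1 kinase, with 68.5 and 79.1 TPM against 37.7 and 22.4 (1.31, adjusted p = 0.0053), a call lost without cKO-labelled replicate 4 or 5. Upf1, Upf3a and Upf3b had log2 fold changes of 0.67, 0.06 and -0.34 and did not pass, and Upf3a turned to -0.03 without cKO-labelled replicate 4 and -0.06 without control replicate 8. Dhx34 (0.87), Smg5 (0.74) and Pnrc2 (-0.97, adjusted p = 0.0579) did not pass either. As a list they passed without control replicate 9 (camera adjusted p = 0.0021), after GC removal (0.0029) and with no filter on low TPM, in a range of 0.002 to 0.711 over 18 alternatives. Paxx, a DNA end-joining factor gene outside the lists, rose by 2.31, a call lost without cKO-labelled replicate 5.

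None of 10 exon junction complex genes passed in limma, over all genes or over the list alone (median -0.20, or -0.04 relative to all genes; camera adjusted p = 0.825). Magoh, Cwc22, Sap18, Magohb and Eif4a3 stood at -0.73, -0.52, -0.51, -0.47 and -0.09, and Eif4a3 turned to 0.07 after median-of-ratios scaling. The direction of the list turned without cKO-labelled replicate 5 or control replicate 9 (adjusted p = 0.888 and 0.797), in a range of 0.34 to 0.937 over 18 alternatives. Magohb turned to 0.04 without control replicate 9 and Eif4a3 to 0.08 without cKO-labelled replicate 5.

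Of 41 p53 target genes 3 rose and none fell, or 4 and 0 adjusted over the list alone. The list's median was -0.05, its mean 0.02 and its camera direction up (adjusted p = 0.298), and the median was 0.11 and 0.05 after median-of-ratios scaling and quantile normalization. The risen genes were the lncRNA Pvt1, Abhd4 and the adenylate kinase gene Ak1, at 1.04, 1.02 and 1.03. None of these calls remained without cKO-labelled replicate 4 or 5, while 2 remained without control replicate 8 and 1 without control replicate 9. Pvt1 was at 0.63 without cKO-labelled replicate 5 and Abhd4 at 0.67 without control replicate 9. Bbc3, which encodes the p53-induced death effector PUMA, had 17.8 and 28.0 TPM against 12.4 and 8.03 (1.09, adjusted p = 0.0533). It stayed uncalled in 10 of 16 alternatives, and its fold change was 0.51 after GC removal (limma adjusted p = 0.22). The canonical targets Cdkn1a and Mdm2 stood at -0.51 and -0.53 (adjusted p = 0.394 and 0.368), and the abundant Btg2 and Rps27l at 0.08 and -0.35, with Rps27l at 0.01 without control replicate 9.

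Of 27 apoptosis genes 1 fell and none rose, with the same counts adjusted over the list alone. The median was -0.15 (0.01 after median-of-ratios scaling), the mean -0.11 and the camera direction up (adjusted p = 0.825), and the direction turned without cKO-labelled replicate 5 (adjusted p = 0.904), in a range of 0.486 to 0.994 over 18 alternatives. The initiator caspase gene Casp8 fell, at -1.55, a call kept only without control replicate 8 among the fits without 1 library. Bad, Bcl2l1, Xiap and Parp1 stood at 0.93 (adjusted p = 0.0706), 0.66, -0.94 and -0.09, and Parp1 turned to 0.08 after median-of-ratios scaling and 0.04 without cKO-labelled replicate 5.

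**Figure D3:**
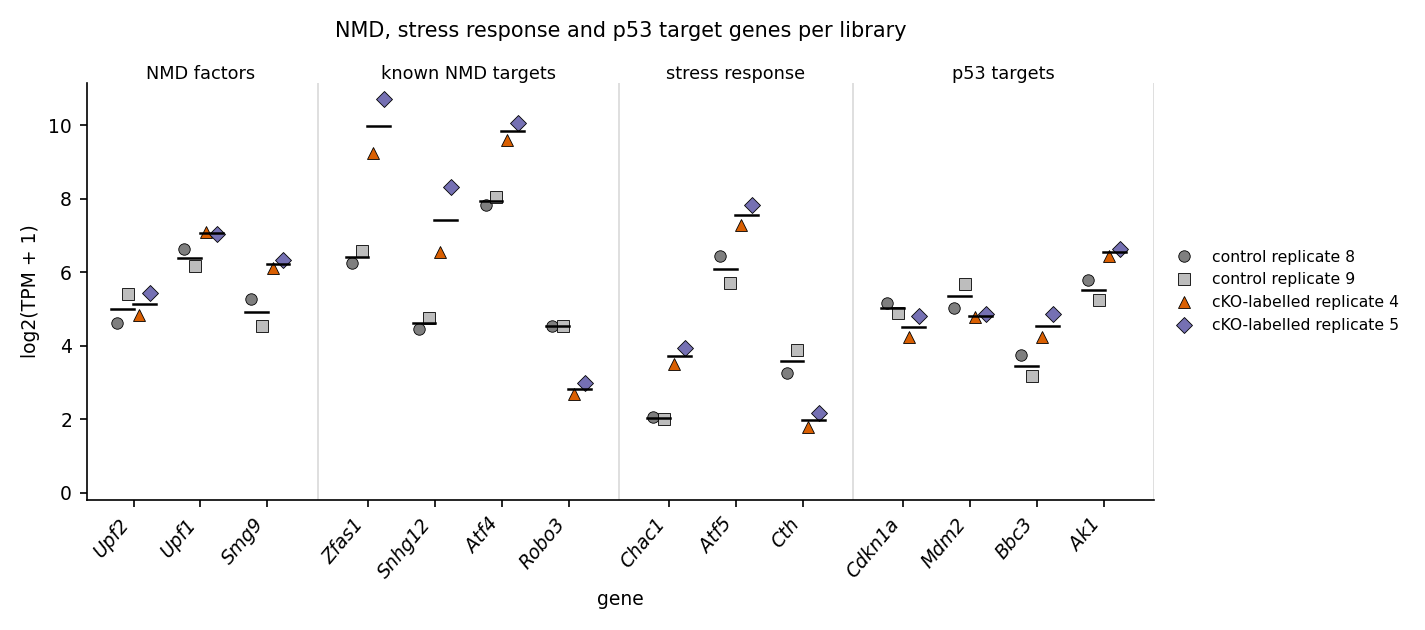
Level of NMD factor, NMD target, stress response and p53 target genes in each library, in log2(TPM + 1), with 1 point per library and a bar at the mean of each group of 2. Zfas1 lies at 75.1 and 95.1 TPM in controls and at 603 and 1677 TPM in the cKO-labelled libraries, and Upf2 overlaps between the groups.

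Proliferation and repair genes were lower as lists, with few single calls. Control replicate 9 had the highest median TPM of the 4 libraries in the G2 and M phase, DNA repair, S phase and splicing lists. Control replicate 8 also lay above both cKO-labelled libraries in all of these but the splicing list, at 85.4 TPM against 54.8 and 64.1 TPM for G2 and M phase. Of 40 G2 and M phase genes 1 fell and none rose, and none passed adjusted over the list alone (median -0.68, or -0.52 relative to all genes; camera adjusted p = 0.000602; adjusted p = 0.737 with an estimated correlation). It was the spindle gene Nusap1, with 53.6 and 69.5 TPM against 87.8 and 173 (adjusted p = 0.0469), while Kif20a, Sgo1 and Ttk stood at -0.93, -0.96 and -0.95. Of 29 DNA repair genes only the checkpoint kinase gene Chek1 fell, at -1.12, and none passed adjusted over the list alone (median -0.58, or -0.42 relative to all genes; camera adjusted p = 0.0097; adjusted p = 0.738 with an estimated correlation). Chek2, Xrcc6 and Atm did not pass, at -0.99, -0.94 and -0.91.

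Of 36 S phase genes only the origin recognition gene Orc1 fell, at -1.17, and none passed adjusted over the list alone (median -0.49, or -0.33 relative to all genes; camera adjusted p = 0.021; adjusted p = 0.737 with an estimated correlation). Pcna stood at -1.01 (adjusted p = 0.0535), and Slbp and Prim1 at -0.97 and -0.93. The S phase call ended without cKO-labelled replicate 5 (adjusted p = 0.157) and after median-of-ratios scaling (adjusted p = 0.0573), in a range of 0.00014 to 0.737 over 18 alternatives. Nusap1, Chek1 and Orc1 each passed without control replicate 8 and in none of the other 3 fits without 1 library. Without control replicate 9 the medians of the G2 and M phase, DNA repair and S phase lists were -0.28, -0.23 and -0.25, with Nusap1 and Chek1 at -0.52 and -0.63, and the list calls remained. Without control replicate 8 the medians of the G2 and M phase and DNA repair lists were -1.07 and -0.92.

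Of 30 splicing regulators with poison exons, exons whose inclusion makes a transcript an NMD target, 2 fell and none rose, or 6 and 0 adjusted over the list alone (median -0.58, or -0.42 relative to all genes; camera adjusted p = 0.0218; adjusted p = 0.804 with an estimated correlation). They were the cold-inducible gene Rbm3 and Srsf5, at -1.08 and -1.03, calls kept only without control replicate 8 among the fits without 1 library. Luc7l3 and Ptbp2 did not pass (-0.99 and -0.96, adjusted p = 0.0515 and 0.0599). The list call ended without cKO-labelled replicate 4 (adjusted p = 0.227), after median-of-ratios scaling (adjusted p = 0.0881) and after removal of the GC trend (adjusted p = 0.261), in a range of 0.00045 to 0.804 over 18 alternatives. The median was -0.36 without cKO-labelled replicate 4, -0.94 without control replicate 8 and -0.24 without control replicate 9, where Rbm3 and Srsf5 stood at -0.54 and -0.64.

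None of 32 primary microcephaly genes passed in limma, over all genes or over the list alone (median -0.43, or -0.27 relative to all genes; camera adjusted p = 0.426). Knl1, Nup37, Cep135 and Kif11 stood at -1.07 (adjusted p = 0.055), -0.97, -0.94 and -0.85, and the abundant Lmnb1 and Ncapd2 at -0.19 and 0.17. Across the list, the median was -0.72 without control replicate 8 and -0.15 without control replicate 9, where Knl1 and Nup37 stood at -0.59 and -0.41.

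Of 36 apical radial glia markers 6 fell and none rose, or 6 and 1 adjusted over the list alone (median -0.09, or 0.08 after median-of-ratios scaling; camera direction down, adjusted p = 0.506). They were Hopx, Aldoc, Emx2, Dmrt3, Hes1 and Lhx2, at -1.89, -1.53, -1.41, -1.43, -1.10 and -1.09. Hopx and Aldoc were at -0.87 and -0.66 without cKO-labelled replicate 4 and at -2.91 and -2.40 without replicate 5, and Hopx at -1.24 without control replicate 9. Emx2, Dmrt3 and Lhx2 are regulators of dorsal and medial telencephalic identity. The abundant Fabp7 and Phgdh stood at -0.05 and 0.43, and Fabp7 turned to 0.12 after median-of-ratios scaling. Without cKO-labelled replicates 4 and 5 and control replicates 8 and 9 in turn, 0, 2, 5 and 4 of the 6 calls remained, and without control replicate 9 Fabp7 and Phgdh turned to 0.50 and -0.08.

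Of 23 intermediate progenitor markers 3 rose and none fell, with the same counts adjusted over the list alone (median 0.06, or 0.22 above all genes; camera adjusted p = 0.0373; adjusted p = 0.737 with an estimated correlation). Gadd45g had 610 and 867 TPM against 174 and 220 TPM in controls (1.89, adjusted p = 9.28e-06), and Mfng and Insm1 rose by 1.17 and 1.02, while Hes6 did not pass at 0.85. The list call ended without cKO-labelled replicate 5 (adjusted p = 0.0949) or control replicate 9 (adjusted p = 0.156), after median-of-ratios scaling (0.0573), quantile normalization (0.16) and GC removal (0.261), in a range of 0.0199 to 0.737 over 18 alternatives. None of the 3 gene calls remained without cKO-labelled replicate 4 or 5, and Mfng was at 0.75 without control replicate 9. The list's median was 0.20 without cKO-labelled replicate 4, and relative to all genes it was 0.34 without control replicate 8 and 0.12 without control replicate 9.

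Of 39 projection neuron markers 3 rose and 1 fell, or 6 and 3 adjusted over the list alone (median 0.39, or 0.54 above all genes; camera adjusted p = 0.011; adjusted p = 0.602 with an estimated correlation). The microtubule gene Mapt had 293 and 246 TPM against 118 and 77.1 TPM (1.48, adjusted p = 0.000733). Pou3f1 and Hs3st4 rose by 1.76 and 1.27, and Crym fell, at -1.89. The list call ended without control replicate 8 (adjusted p = 0.0635) and after quantile normalization (adjusted p = 0.0542), in a range of 0.000451 to 0.602 over 18 alternatives. None of the 4 gene calls remained without cKO-labelled replicate 4 or 5, and 3 remained without control replicate 9. The list's median was 0.21 without control replicate 8, and 0.35 above all genes without control replicate 9.

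Of 17 Cajal-Retzius markers 2 fell and none rose, or 2 and 2 adjusted over the list alone (median 0.03, mean -0.02, camera direction up with adjusted p = 0.56). Zic1, also expressed in medial telencephalon and meninges, fell, at -1.86. It was at -0.58 without cKO-labelled replicate 4 and -3.15 without replicate 5. Barhl2, Spock1 and Cxcr4 stood at 1.07, 0.99 and -0.77 and did not pass. Zic1 passed without cKO-labelled replicate 5 and in none of the other 3 fits without 1 library, and the list's direction turned without cKO-labelled replicate 5 (adjusted p = 0.904), in a range of 0.0573 to 0.96 over 18 alternatives.

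Of 24 Notch, Wnt and Shh readouts 5 fell and none rose, or 7 and 1 adjusted over the list alone (median -0.36, or -0.21 relative to all genes; camera adjusted p = 0.145). The Wnt targets Sp5, Rnf43 and Axin2 fell, at -1.97, -1.59 and -1.37, as did the Notch effectors Hey2 and Hes1, at -2.33 and -1.10. The abundant Ccnd1 and Hes5 stood at 0.71 and 0.47. Across the list, the median was -0.05 without control replicate 8 and -0.59 without control replicate 9, or 0.2 and -0.54 relative to all genes. The list passed without cKO-labelled replicate 4 (adjusted p = 0.0245), without control replicate 9 (0.0032) and after GC removal (0.000739), in a range of 0.000522 to 0.933 over 18 alternatives. Without cKO-labelled replicate 4 or 5, 2 of the 5 gene calls remained.

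Of 9 oligodendrocyte precursor and astrocyte markers 2 rose and 2 fell, or 3 and 2 adjusted over the list alone (median 0.29, or 0.44 above all genes; camera adjusted p = 0.181). Olig2, also a ventral progenitor gene, and Aldh1l1 rose by 2.26 and 1.77, while Pdgfra, also on the meningeal list, and Sparcl1 fell, at -2.20 and -1.51. Without cKO-labelled replicate 4 or 5, 1 and 2 of the 4 calls remained. The list passed with a mean TPM of at least 5 (adjusted p = 0.0374), in a range of 0.0374 to 0.737 over 18 alternatives.

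Of 24 endothelial and pericyte markers 3 fell and none rose, or 5 and 1 adjusted over the list alone (median -0.32, or -0.16 relative to all genes; camera adjusted p = 0.119). They were Vtn, Tek and Emcn, at -2.01, -1.21 and -1.20, and none of these calls remained without cKO-labelled replicate 4 or 5, while 2 remained without control replicate 9. Vtn was at -1.28 without control replicate 8. Higd1b, Cldn5 and Slc2a1 stood at 0.91 (adjusted p = 0.0525), 0.14 and -0.15, with Cldn5 at -0.42 without control replicate 9 and Slc2a1 at 0.16 without control replicate 8 and 0.01 after median-of-ratios scaling. The list passed without cKO-labelled replicate 4 (adjusted p = 0.0126), without control replicate 9 (0.000176) and after GC removal (0.000317), in a range of 2.3e-05 to 0.82 over 18 alternatives.

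Of 17 red blood cell genes only Car2 fell and none rose, or 4 and 1 adjusted over the list alone (median -0.52, or -0.37 relative to all genes; camera adjusted p = 0.0904). Car2 stood at -1.50, a call kept only without control replicate 8 among the fits without 1 library. Slc25a37 and Rhd did not pass, at -1.08 and -0.85. The globin genes Hba-a1 and Hbb-y stood at -0.32 and -0.05, and both turned without cKO-labelled replicate 5 (0.25 and 0.59) or control replicate 8 (0.37 and 0.35). Hbb-y also turned after median-of-ratios scaling, to 0.12. Across the list, the median was -0.89 and -0.26 without cKO-labelled replicates 4 and 5, and -0.26 and -0.91 without control replicates 8 and 9. The list passed without cKO-labelled replicate 4 (adjusted p = 0.000375), without control replicate 9 (0.000185), after GC removal (0.0045) and with no filter on low TPM (0.0199), in a range of 0.000185 to 0.933 over 18 alternatives.

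Of 16 interferon-stimulated genes only B2m fell and none rose, or 2 and 0 adjusted over the list alone (median -0.43, or -0.28 relative to all genes; camera adjusted p = 0.178). B2m stood at -1.30, a call lost without cKO-labelled replicate 4 or 5. Ifi27, Eif2ak2, Dhx58 and H2-D1 did not pass, at -1.02, -0.89, -0.76 and -0.12, and H2-D1 turned to 0.17 without control replicate 8 and 0.04 after median-of-ratios scaling. Interferon-stimulated genes passed as a list without control replicate 9 (adjusted p = 0.0194), in a range of 0.014 to 0.737 over 18 alternatives. The thalamus list had 3 tested members of 20, too few for a list test, and none passed over all genes, while 1 was lower adjusted over the list alone. Lhx9, Tal1 and Tcf7l2 stood at -1.04, -0.45 and 0.17.

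Of 28 hypoxia and glycolysis genes 1 rose and 1 fell, with the same counts adjusted over the list alone (median -0.37, or -0.21 relative to all genes; camera adjusted p = 0.337). Ndrg1 rose by 1.74 and Pdk1 fell, at -1.15, calls lost without cKO-labelled replicate 4 or 5, and that of Pdk1 also without control replicate 9. P4ha2, Vegfa, Gapdh and Mif stood at -0.96, -0.87, -0.14 and 0.00, and without control replicate 8 Gapdh and Mif were at 0.34 and 0.35. After median-of-ratios scaling Gapdh was at 0.02. The list passed without control replicate 9 (adjusted p = 0.00047) and after GC removal (0.0029), in a range of 0.000319 to 0.774 over 18 alternatives.

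None of 20 immediate early and heat shock genes passed in limma, over all genes or over the list alone (median 0.06, mean -0.01, camera direction up with adjusted p = 0.506). Dusp1, Nr4a1, Jund, Egr1, Hsp90aa1 and Hspa8 stood at 0.74, 0.73, 0.66, -0.78, -0.66 and -0.48. The list's direction turned without control replicate 9 (adjusted p = 0.679), in a range of 0.197 to 0.96 over 18 alternatives.

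None of 76 ribosomal protein genes passed in limma by either count (median -0.27, or -0.11 relative to all genes; camera adjusted p = 0.574). Rpl17, Rps6, Rps24, Rpl5, Rplp0 and Rps15 stood at -0.81, -0.79, -0.77, -0.75, -0.10 and 0.04. Rplp0 turned to 0.30 without control replicate 8 and 0.07 after median-of-ratios scaling, and Rps15 to -0.26 without control replicate 9 and -0.02 after quantile normalization. Ribosomal protein genes passed as a list without control replicate 9 (adjusted p = 0.0262), in a range of 0.014 to 0.864 over 18 alternatives. None of 10 mitochondrial mRNAs passed in limma by either count (median -0.49, or -0.34 relative to all genes; camera adjusted p = 0.31). The genes mt-Nd6, mt-Atp6, mt-Co2 and mt-Co3 stood at -0.89, -0.69, -0.66 and -0.66, and mt-Co1 and mt-Cytb at -0.14 and -0.05, with both above 0 without cKO-labelled replicate 4 (0.09 and 0.07), without control replicate 9 (0.05 and 0.03) and after median-of-ratios scaling (0.03 and 0.12).

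**Figure D4:**
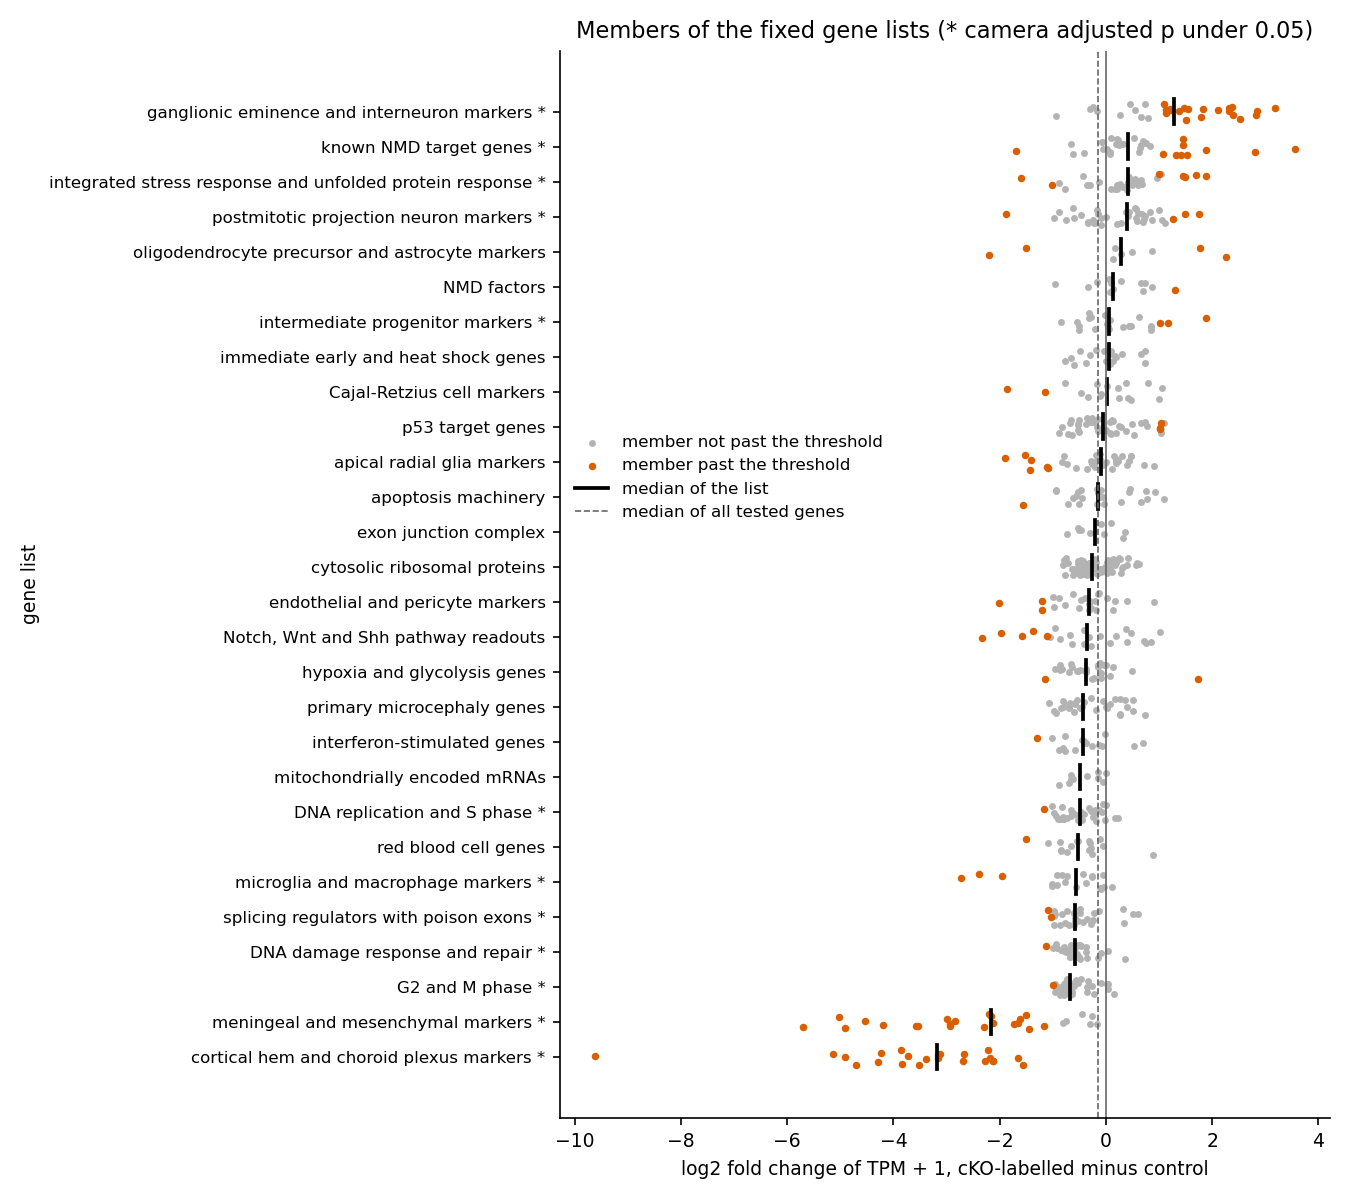
Log2 fold change of TPM + 1 (cKO-labelled minus control) of each tested member of the 28 tested lists, with 1 point per gene, a black bar at each list's median and a dashed line at the median of all tested genes, -0.16. The hem and choroid plexus list (median -3.17) and the meningeal list (-2.16) lie farthest below 0, and the ganglionic eminence list (1.29) farthest above.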

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

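The GC removal and its combination with leaving out control replicate 9 were chosen after seeing the data. No paired analysis was possible because the groups share no replicate numbers. The cause of the shifts was not tested unless a clause gives it. Against 1229 calls (438 higher, 791 lower), no filter on low TPM gave 178 (4 and 174), with 26133 genes tested and finite prior degrees of freedom of 4.95. A mean TPM of at least 5 gave 642, with 328 lower and 11304 genes tested. Median-of-ratios scaling gave 772 higher and quantile normalization 714 higher. Without control replicate 9 and with the GC trend removed, 814 genes were called, 486 of them lower. Leaving out each library in turn gave 176 to 7379 calls, 18 to 2830 higher and 158 to 4549 lower. The other settings kept each of these counts within 1.5 times, and voom on recovered reads, with 14964 genes, called 1317. An added fold change threshold of 1 on the log2 scale left 1193.

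The 12 list calls became 0 with an estimated correlation and 2 with fry (hem and choroid plexus, and projection neurons), and numbered 9 to 18 elsewhere. In the self-test an estimated correlation recovered none of the lists shifted by 0.5, but genes there were simulated independently and larger shifts were not tried. The correlation estimated here was 0.47 for the ganglionic eminence, 0.58 for the G2 and M phase and 0.17 for the hem and choroid plexus list, above the preset 0.01. The self-test therefore cannot tell whether these calls ended through low power or through real correlation between genes. The hem and choroid plexus list was called in 17 of 18 alternatives, and the meningeal, ganglionic eminence and known NMD target lists in 16.

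Of 81 named calls, the alternatives that keep all libraries kept 18 (no filter on low TPM) to 81. No named call changed sign in any alternative. Called genes mostly had large fold changes and groups that did not overlap, so a constant sign is little support. Of 169 named genes tested, 23 turned sign in at least 1 alternative, none of them called. Without each library in turn, Upf2 ranged from -0.26 to 0.52, Upf3a from -0.06 to 0.17, Kdm5d from -0.76 to 0.01, Eif4a3 from -0.26 to 0.08, Fabp7 from -0.60 to 0.50, Gapdh from -0.63 to 0.34, H2-D1 from -0.41 to 0.17, Hbb-y from -0.69 to 0.59, Mif from -0.35 to 0.35, mt-Co1 from -0.36 to 0.09 and mt-Cytb from -0.17 to 0.07. Parp1 ranged from -0.21 to 0.04, Rplp0 from -0.50 to 0.30, Slc2a1 from -0.46 to 0.16, Rps15 from -0.26 to 0.34, Cldn5 from -0.42 to 0.71, Magohb from -0.99 to 0.04, Phgdh from -0.08 to 0.94 and Rps27l from -0.71 to 0.01. Hba-a1 ranged from -1 to 0.37, and was 0.25 without cKO-labelled replicate 5.

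Median-of-ratios scaling, which raises all fold changes, turned Eif4a3 to 0.07, Fabp7 to 0.12, Gapdh to 0.02, H2-D1 to 0.04, Hbb-y to 0.12, Mif to 0.16, mt-Co1 to 0.03, mt-Cytb to 0.12, Parp1 to 0.08, Rplp0 to 0.07 and Slc2a1 to 0.01. Quantile normalization turned Mif to 0.15 and Rps15 to -0.02, and voom turned Mif to 0.02. GC removal turned Cldn5 to -0.31, Fabp7 to 0.43, Hbb-y to 0.15, Hes5 to -0.03, Kdm5d to 0.06, Magohb to 0.02, mt-Co1 to 0.41, mt-Cytb to 0.51, Rps15 to -0.47, Rps27l to 0.11 and Upf3b to 0.14. GC removal without control replicate 9 turned Cldn5 to -0.58, Fabp7 to 0.63, Hes5 to -0.07, Kdm5d to 0.13, Magohb to 0.18, mt-Co1 to 0.23, mt-Cytb to 0.23, Phgdh to -0.15, Rps15 to -0.48, Rps27l to 0.13, Sap18 to 0.00 and Upf3b to 0.08.

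Of the lists, 5 turned direction in at least 1 alternative, none of them called. The apoptosis list turned with fry, quantile normalization and GC removal (adjusted p = 0.486, 0.994 and 0.931), the Cajal-Retzius list with fry and a mean TPM of at least 5 (0.96 and 0.558), and the immediate early list with fry, GC removal and both changes (0.96, 0.389 and 0.306). The exon junction list turned with both changes (0.605) and the mitochondrial list with GC removal (0.521). Without each library in turn, their adjusted p ranged from 0.679 to 0.933 for apoptosis, from 0.0573 to 0.904 for Cajal-Retzius, from 0.304 to 0.819 for immediate early and from 0.574 to 0.888 for exon junction genes.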

Other observations

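Tests chosen only after the result was seen are those of the Emx1-Cre lineage, of tissue borders, of GC content in the meningeal and ganglionic eminence lists, of ganglionic eminence tissue as a source of NMD targets, and of control replicate 9 as the source of the proliferation pattern, and of why ganglionic eminence calls ended, together with every value after GC removal. Emx1, the gene whose promoter names the Cre line, had 84.9 and 116 TPM in the cKO-labelled libraries and 191 and 130 TPM in controls (-0.66, limma adjusted p = 0.23), and it passed after GC removal (-1.27, adjusted p = 0.0143) and without control replicate 9 (adjusted p = 0.0285), in a range of 0.0143 to 1.00 over 16 alternatives. Y-linked genes were detected in all 4 libraries, and Xist lay between 0.27 and 0.46 TPM, so the groups did not differ in the presence of a Y chromosome. Of the 4 tested sex-specific genes Ddx3y fell and 2 fell adjusted over the list alone, with 10.1 and 15.5 TPM for Ddx3y against 25.9 and 48.6 TPM in controls (-1.43), a call kept only without control replicate 8 among the fits without 1 library. Eif2s3y, Uty and Kdm5d stood at -0.86, -0.79 and -0.37, and Kdm5d at 0.01 without control replicate 9. Tsix was at 0 TPM in both cKO-labelled libraries and at 0.01 and 0.07 TPM in controls.

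The hem and choroid plexus and the meningeal lists were lower in the cKO-labelled libraries, with 23 of 23 and 21 of 27 members called, and the ganglionic eminence list higher, with 20 of 30 called, but no list passed with an estimated correlation (adjusted p = 0.202, 0.202 and 0.602). A GC trend as the whole cause is argued against by the medians after its removal: -3.33 for hem and choroid plexus (bootstrap interval -4.10 to -2.43), -1.96 for meninges (-2.62 to -1.50) and 1.50 for ganglionic eminence (1.06 to 1.93, against 1.29 and 0.94 to 1.81 before). These and later bootstrap intervals resample genes, not libraries. Only 6 of the 20 ganglionic eminence calls remained after GC removal. With the fold changes after removal and the spread before it 18 remained. With the fold changes before and the spread after (prior degrees of freedom 5.87 in place of infinite) 13 remained. All 20 did with the pooled spread after, a fit with 4010 calls in all. Spread and fold changes thus both bear on the loss: 13 of the 20 fold changes became smaller, although the median of the 20 rose from 1.81 to 1.93. The meningeal median of -2.16 is itself part of the pattern. Since meninges lie outside the Emx1-Cre lineage, it argues only against loss of that lineage alone as the cause of the meningeal fall. It says nothing about the cause of the hem and choroid plexus fall. Different tissue borders in the dissections cannot be told apart from genotype, itself untested, with 2 libraries each: the meningeal minus ganglionic eminence median of -3.45 only restates the pattern, and the ganglionic eminence median differed by 0.80 within the cKO-labelled pair and 0.72 within the control pair, less than the 1.29 between the groups (0.76 without control replicate 8, 2 without control replicate 9), where a difference at least as large had been predicted.

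The list of known NMD target genes was higher in the cKO-labelled libraries, with 9 of 34 members risen (camera adjusted p = 4.64e-08; adjusted p = 0.644 with an estimated correlation). All 9 risen members kept a log2 fold change above 0.5 after GC removal, with 8 still called, which argues against GC bias between libraries as the cause. Ganglionic eminence tissue as a source stays open, because the order within the cKO-labelled pair and within the control pair differed. In the cKO-labelled pair 0 of the 9 were higher in replicate 4, where all 20 risen ganglionic eminence markers were higher. That met the bound set for arguing against such tissue as the source, but the bound did not cover the control pair. In the control pair 24 of 30 ganglionic eminence markers were higher in replicate 9 than in 8. There Zfas1, Snhg12, Atf4, Snhg15, Snhg1, Snhg5 and Ddit3 were also higher, while Snhg8 was lower and Pdrg1 was level. Lower NMD activity may contribute: after GC removal 53 coding genes with an intron in the 3' UTR (median 0.17, interval 0.01 to 0.34, percentile 99.3 of 10000 random lists matched on expression, 7 called higher and 1 lower) and 2513 with 3 or more upstream ATGs (0.06 against a random median of -0.02, percentile 100) lay above random lists, but the second shift is small, with 157 called higher and 128 lower after GC removal and 100 and 127 before it, and neither test removes differences in cell types. The 19 other snoRNA host lncRNAs showed no rise before GC removal (median -0.40, percentile 6.2) or after it (median -0.05, percentile 28.7). The percentile before lay inside the central 95% predicted for no effect. The class stays open because its interval reached above the random 95th percentile, with -0.70 to 0.19 against 0.15 before and -0.32 to 0.63 against 0.3 after. The prediction did not name that condition. By the same condition the class with an intron in the 3' UTR stays open too. Its interval of 0.01 to 0.34 reached below its random 95th percentile of 0.11.

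The G2 and M phase, DNA repair and splicing lists were lower in the cKO-labelled libraries, but only 1 of 40, 1 of 29 and 2 of 30 members were called, and the list calls ended with an estimated correlation (adjusted p = 0.737, 0.738 and 0.804). Their pooled median over 99 genes, relative to all genes, was -0.48. Control replicate 9, with the highest medians in these lists, may account for much of it: without that library the median was -0.23, 47% of the full value. That value lay under the bound of 50% set for it, but its bootstrap interval over genes, 40% to 55%, crossed the bound. All 3 lists stayed called. Without control replicate 8 the G2 and M phase median relative to all genes was -0.83 instead. Leaving out the highest library tends to shrink the gap, so with 2 controls the test cannot decide. After GC removal the pooled median was -0.29, 61% of the full value (interval over genes 48% to 71%), which leaves a GC trend open as a cause of part of the pattern. The G2 and M phase and DNA repair lists nevertheless stayed called (camera adjusted p = 4.45e-05 and 0.000701). The splicing list alone of the 3 lost its call (camera adjusted p = 0.261). A lower share of cycling cells with the genotype stays open as an untested explanation.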
